A study of Escherichia coli with 9 samples.

How the data were processed

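Gene expression of Escherichia coli K-12 MG1655 was measured on 2-colour DNA microarrays with RNA from cultures in a defined minimal medium. Per the labels, 3 independently grown cultures of 50 mL were used for each of 3 conditions: no added copper, 0.75 mM copper glycine and 2 mM copper glycine. Cells were taken at an OD600 of 0.8. Channel 1 of each of the 9 arrays held the RNA of one culture. Channel 2 held one common pool of RNA, made from 5 cultures without added copper, so the pool is a reference and was not counted as a sample.

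The deposited values are log2 ratios, one column per array, over 14400 spots in 48 blocks of 300. The base of the logarithm was settled from the values: 100% of the ratios recovered with base 2 are multiples of 0.001 within 1e-06. The scanner software, background correction and normalization are not given in the sources used here. The medians of the deposited columns ranged from -0.67 to 0.58 over all spots and from -0.67 to 0.67 over gene spots, so the arrays had not been centred on a common level. No spot intensities were used here, so the distance of a spot from background is unknown and the number of arrays limits the precision.

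The dyes are not given in the sources used here. The labels put the culture RNA in channel 1, so the likely direction of each ratio is culture over pool. A check fixed before the data were examined took this direction if at least 5 of 6 copper efflux genes were higher at 2 mM than without added copper; 6 of 6 were. Those 6 genes are therefore no independent evidence of direction. Scale is known from the values, centring was done here, and direction rests on this check.

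Of the spots, 9012 had one gene symbol in the platform annotation, none had several and 5388 had none. Symbols were updated through gene identifiers to the RefSeq gene table of assembly ASM584v2; 8924 spots matched and 88 did not. The files name no genome build, so the table served only for names and for the order of neighbouring genes, and no coordinates are given. After the spot layout was seen, 576 control spots, which print 12 genes many times over (312 of them dnaK), were left out. The 8348 remaining spots gave 4131 genes, 4093 of them with 2 spots. Spots of a gene were averaged on each array. The correlation of the 2 spots over genes was 0.79 to 0.94 per array, and their median absolute difference 0.08 to 0.14 on the log2 scale.

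Each array was centred on the median of its genes, so every change is relative to the median gene. Genes with values on at least 2 of the 3 arrays in each group were kept, which left out 3 and kept 4128. A linear model with a mean per group was fitted over all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). All adjusted p-values of genes are Benjamini-Hochberg values from limma's moderated test, 2-sided, with a threshold of 0.05. The median standard error was 0.24 on the log2 scale with 10.3 degrees of freedom. The comparisons were each copper level with no added copper, the 2 copper levels with each other, and the cultures without added copper with the pool (mean ratio against 0).

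Before the data were examined, 30 lists with 576 genes were written down from textbook knowledge; 573 of these genes had values. The lists cover copper efflux, other copper-linked genes, iron uptake, iron-sulfur assembly, zinc, envelope, oxidative, heat and DNA damage stress, amino acid and purine synthesis, nitrogen limitation, central metabolism and respiration, flagella, ribosomal proteins, acid resistance, general stress, phage shock, colanic acid and porins. They were tested with limma's camera at its preset correlation between genes of 0.01, over the 4088 genes with a value on all arrays, and again with the correlation estimated per list, and with fry. Adjusted p-values of lists are over the 30 lists.

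Named genes followed a rule fixed in advance. For each copper level against no added copper it takes the 12 largest rises and 12 largest falls among genes past the threshold whose 3 arrays of one group all lie beyond those of the other, and 5 and 5 between the copper levels. It adds the 6 copper efflux genes and up to 4 members, by absolute moderated t, of every other list past its threshold. Genes named outside this rule are said to be chosen after their values were seen.

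The model was tested on simulated data built from the real spread and missing values of the 4128 genes for the comparison of 2 mM with no added copper, with 200 genes changed. Over 20 simulations, 54.1% of the 2-fold changes and 92.35% of the 4-fold changes were recovered, and 4.69% of the calls were false. The flagella and chemotaxis list, shifted 2-fold on the 0.75 mM arrays, was recovered in 100% of them in the comparison of 0.75 mM with no added copper. Genes were simulated as independent, whereas the correlation estimated for this list in the real data was 0.23. The simulations therefore do not test camera on correlated genes.

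Alternatives set in advance were the values as deposited, quantile normalization, equal spread per array, filters, the median of spots, only the 6 arrays compared, a replicate block, array weights, a robust prior, a 2-fold minimum, the pool in place of the control arrays, the other list tests and each array left out in turn. Block-wise centring, centring on all spots, keeping the control spots and leaving out discordant spots were added after seeing the data. Neighbouring genes were taken in genome order, and runs of at least 4 called alike were compared with 10000 permutations of the calls over the genes.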

Results

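The series compared gene expression of Escherichia coli K-12 grown without added copper and with 0.75 mM or 2 mM copper. RNA from 9 cultures was hybridised, one culture per array, against a common pool from cultures without added copper. There were 3 arrays each for no added copper, 0.75 mM and 2 mM copper, and copper was added as its glycine complex, so glycine rose with copper. Arrays of the same group correlated at 0.36 to 0.83 and arrays of different groups at 0.10 to 0.55; these are correlations across genes, which are not independent replicates. On the array labelled Cu 0.75 mM replicate 3, several heat shock genes lay far above their level on the other arrays (dnaK, chosen after its values were seen, at a log2 ratio of 1.88, against -0.35 to 0.50 elsewhere).

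At 2 mM copper, genes that remove copper from the cell rose, and 4 of them (cusF, cusC, copA and cusB) had the largest rises among the named genes. All 6 copper efflux genes were higher than without added copper (6 adjusted over the list alone), by 4.91 on average on the log2 scale. The cytoplasmic copper exporter gene copA rose 46.8-fold (log2 change 5.55 ± 0.22 SE, n = 3 arrays per group, limma adjusted p = 4.72e-07). The periplasmic efflux genes cusF and cusC rose 112-fold and 64.7-fold, cusB 40.7-fold and cusA 11.1-fold, and the multicopper oxidase gene cueO 4.79-fold. The list's shift passed camera (adjusted p = 3.51e-13, and 0.027 with an estimated correlation), but these genes also set the direction of the ratios and are no independent evidence of it. Of 17 other copper-linked genes 6 rose and none fell (7 and 0 adjusted over the list alone), among them cusR (14.7-fold) and cusS (7.42-fold), the sensor-regulator pair of the cus genes, and hprR (5.48-fold, log2 change 2.45, and 1.38 and not past the threshold with quantile normalization). That list passed camera (adjusted p = 1.42e-05), with an adjusted p = 0.17 with an estimated correlation.

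Genes of iron-sulfur cluster assembly and iron acquisition were also higher at 2 mM. In the assembly list 10 of 14 rose and none fell (12 and 0 adjusted over the list alone), with a mean log2 change of 1.89. Among the largest rises in the list were suf genes, which encode the assembly system used under iron limitation and oxidative stress: sufD 13.7-fold, sufA 11.6-fold, sufC 9.57-fold (2 arrays at 2 mM) and sufS 7.76-fold. In the iron uptake list 20 of 44 rose and 1, efeO (chosen after its value was seen), fell (27 and 3 adjusted over the list alone). Its members with the largest moderated t included nrdH, nrdI and nrdF (15.0-fold, 13.0-fold and 11.7-fold), which encode a manganese-using ribonucleotide reductase system and its partners rather than uptake proteins, and entD (2.57-fold) of enterobactin synthesis. Both lists passed camera (adjusted p = 1.89e-11 and 8.49e-12), each with an adjusted p = 0.12 with an estimated correlation. The iron superoxide dismutase gene sodB fell by 3.88 on the log2 scale (SE 0.22, adjusted p = 3.66e-06). Of the superoxide stress genes 4 of 17 rose and none fell (7 and 1 adjusted over the list alone): soxS, a transcription activator, 11.2-fold, fpr 2.93-fold, fldA (flavodoxin) 2.41-fold and zwf 1.69-fold. With quantile normalization the log2 changes of fpr, fldA and zwf were 0.96, 0.61 and 0.72 and did not pass, nor did fldA and zwf in the values as deposited. That list passed camera (adjusted p = 0.014), with an adjusted p = 0.30 with an estimated correlation.

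The envelope stress genes of the Cpx pathway rose as well. Of 18 members 12 rose and none fell (14 and 0 adjusted over the list alone), with a mean log2 change of 1.45. The periplasmic chaperone gene spy rose 31.7-fold (log2 change 4.99 ± 0.29 SE), ldtC 10.8-fold, the membrane protease gene htpX 5.07-fold and yebE by a log2 change of 2.48. The list passed camera (adjusted p = 1.65e-11) and also with an estimated correlation (adjusted p = 0.012). Outside the lists, the rises among the 12 largest included raiA (14.9-fold), whose protein binds inactive ribosomes, and ptrB (12.2-fold), an oligopeptidase gene. Also outside the lists was grcA, first among the 12 largest falls at 2 mM, with a log2 change of -4.06.

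Motility and respiration genes were lower at 2 mM. Of 48 flagellar and chemotaxis genes 37 fell and none rose (43 and 0 adjusted over the list alone), with a mean log2 change of -1.43. The flagellin gene fliC fell by 3.82 on the log2 scale (SE 0.21, adjusted p = 2.9e-06), and the chemotaxis genes cheW and cheA had log2 changes of -2.85 and -2.57. The list passed camera (adjusted p = 1.61e-34, and 0.042 with an estimated correlation). In the list of respiratory oxidases and NADH dehydrogenases 15 of 23 fell and 1 rose (19 and 1 adjusted over the list alone), with a mean of -1.30. Those that fell included nuoK, nuoF, nuoG and nuoC of the proton-pumping NADH dehydrogenase, with log2 changes of -2.52, -2.32, -2.32 and -2.07, whereas ndh, encoding the dehydrogenase that pumps no protons, rose by 1.19 (chosen after its value was seen). The list passed camera (adjusted p = 3.81e-16), with an adjusted p = 0.12 with an estimated correlation. Among 16 TCA cycle genes 5 fell and 1 rose (8 and 1 adjusted over the list alone), with sucB at -1.47 and sucC at -1.16, neither past the threshold in the values as deposited. The list passed camera (adjusted p = 8.4e-05), with an adjusted p = 0.23 with an estimated correlation.

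Of 54 ribosomal protein genes 24 fell, 1 rose and 29 did not pass (31 fell and 1 rose adjusted over the list alone), with a mean log2 change of -0.61. Among those that fell were rplD (-1.40), rplO (-1.19) and rpsS (-1.05), none of them past the threshold in the values as deposited. The one that rose was rpmE (3.69-fold), which encodes the zinc-binding form of ribosomal protein L31. Its paralog without the zinc-binding cysteines, ykgM, fell by 3.99 (SE 0.20, adjusted p = 1.94e-06). The ribosomal list passed camera (adjusted p = 6.27e-14), with an adjusted p = 0.23 with an estimated correlation. With quantile normalization the change of rpmE was 0.17 and did not pass. In the zinc list, which did not pass (adjusted p = 0.098), 4 of 14 genes fell and none rose (4 and 1 adjusted over the list alone): ykgM, the periplasmic zinc-binding protein gene zinT (-3.23), and znuA and znuC of the zinc importer (-1.63 and -1.01, chosen after their values were seen). The list's mean (-0.55) and median (0.13) differ in sign.

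Acid resistance genes fell: 7 of 14 fell and none rose (9 and 0 adjusted over the list alone), with a mean log2 change of -1.42. The periplasmic acid chaperone gene hdeA fell by 3.96 (SE 0.28), and the glutamate decarboxylase gene gadB and the antiporter gene gadC had log2 changes of -3.51 and -1.98. The list passed camera (adjusted p = 4.39e-08), with an adjusted p = 0.11 with an estimated correlation. Smaller shifts passed for 6 further lists, each lost with an estimated correlation. Of 14 purine synthesis genes 3 fell and none rose (5 and 0 adjusted over the list alone), with guaB at -1.34 (adjusted p = 0.17 with an estimated correlation). Of 8 histidine genes 2 fell and none rose (3 and 0 adjusted over the list alone), with hisC at -0.99 and hisH at -0.94 (adjusted p = 0.37 with an estimated correlation). In the next 4 lists the mean was below 0 after centring but slightly above 0 in the values as deposited. Centring subtracts 1 value per array from every gene, so all list means of a comparison move by the same amount. The turns show only that the sign of such small means depends on centring, and are no separate test of each list. Of 22 colanic acid genes 4 fell and none rose (4 and 0 adjusted over the list alone), gmd at -1.81, with a mean of -0.33 against 0.0059 as deposited (adjusted p = 0.38 with an estimated correlation). Of 12 arginine genes 2 fell and 1 rose (6 and 2 adjusted over the list alone), carA at -1.35, with a mean of -0.33 against 0.0040 as deposited (adjusted p = 0.15 with an estimated correlation). Of 28 anaerobic respiration genes 3 fell and none rose (4 and 0 adjusted over the list alone), pflB at -1.35, with a mean of -0.32 against 0.015 as deposited (adjusted p = 0.17 with an estimated correlation). Of 20 general stress genes 5 fell and 1 rose (7 and 1 adjusted over the list alone), katE at -1.22, with a mean of -0.26 against 0.070 as deposited (adjusted p = 0.44 with an estimated correlation).

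The other lists did not pass at 2 mM (camera adjusted p from 0.092 upward), although single members did. Of the branched-chain amino acid genes 3 rose and 1 fell (6 and 2 adjusted over the list alone), of the porins 3 and 3 (3 and 3 adjusted over the list alone), with ompW at -2.97, and of the glycine, serine and one-carbon genes 3 rose and none fell (3 and 0 adjusted over the list alone). Those 3 are gcvT, gcvH and gcvP of the glycine cleavage system, with log2 changes of 1.85, 1.38 and 1.05 (chosen after their values were seen). In the methionine list 2 rose and 1 fell (2 and 1 adjusted over the list alone), in the phage shock and sigma E lists 2 rose and none fell (3 and 2 rose adjusted over the list alone), and in the peroxide list 2 fell and none rose (2 and 1 adjusted over the list alone). In each of the aromatic amino acid, cysteine and nitrogen limitation lists 1 rose and 1 fell, with the same counts adjusted over the list alone. No member of the heat shock list (16 genes) or the SOS list (19 genes) passed limma's test. That test took its spread from all 9 arrays, including Cu 0.75 mM replicate 3 with its high heat shock genes. This widens the standard errors of those genes, so the absence of calls in the heat shock list is weak evidence of no change.

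In all, 413 genes changed at 2 mM against no added copper: 207 rose and 206 fell, and 279 of the 413 changed at least 2-fold. For 1337 genes (32.4%) the arrays of the groups did not overlap, against 10% by chance. The count was 265 (103 higher, 162 lower) with quantile normalization, 143 (102 higher, 41 lower) in the values as deposited and 363 (140 higher, 223 lower) with centring on all spots. Without centring the median of all genes shifted by 0.39 in this comparison, 0.51 at 0.75 mM and -0.11 between the levels. Of the 75 named genes past the threshold 31 lost it in the values as deposited (msrP, fldA, zwf, gmd, gmm, wcaC, ugd, hisC, hisH, argD, carA, argE, guaB, purD, guaA, sucB, sucC, sdhD, sdhC, pflB, dmsB, adhE, flgK, rplO, rplD, rpsS, gadW, wrbA, katE, otsA and osmB) and 16 with quantile normalization (hprR, fldA, fpr, zwf, wcaC, ugd, hisH, argE, purD, guaA, sdhC, pflB, dmsB, adhE, rpmE and osmB). The superoxide, colanic acid and histidine lists were lost with quantile normalization, and the histidine, arginine and general stress lists as deposited. Leaving out Cu 2 mM replicate 2 left 258 genes, no added Cu replicate 1 267 and replicate 3 274. In at least one fit without an array 15 of the 75 named genes past the threshold lost it (zwf, wcaC, ugd, hisC, hisH, argE, purD, guaA, adhE, osmB, fpr, sdhD, sdhC, pflB and dmsB), as did the colanic acid, histidine, arginine and general stress lists.

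**Figure D1:**
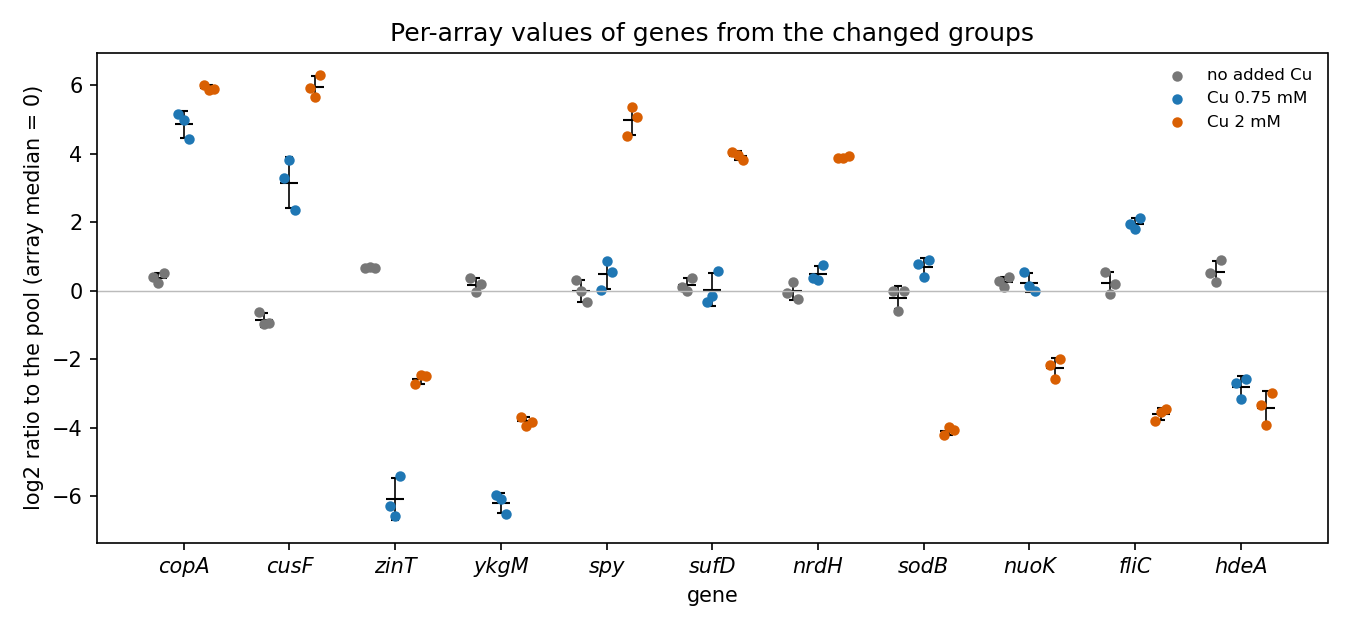
Log2 ratio to the pool, with each array's median gene at 0, for 11 genes (x axis) on the 9 arrays; points are single arrays coloured by group, and dashes and bars give the mean and SD of the 3 arrays per group. The zinT values at 0.75 mM (mean -6.08) lie below those at 2 mM (mean -2.56), and fliC is higher at 0.75 mM (mean 1.96) and lower at 2 mM (mean -3.60) than without added copper (mean 0.23).

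At 0.75 mM copper, the copper efflux genes again rose, and zinT and ykgM of the zinc list had the largest falls. All 6 copper efflux genes rose (6 adjusted over the list alone), with a mean log2 change of 3.63: copA 22.4-fold (log2 change 4.48 ± 0.22 SE, limma adjusted p = 1.34e-06), cusC 17.4-fold, cusF 16.1-fold, cusB 15.5-fold, cusA 7.15-fold and cueO 5.26-fold. In the zinc list 4 of 14 genes fell and none rose (5 and 0 adjusted over the list alone). zinT fell by 6.75 on the log2 scale (SE 0.27, adjusted p = 3.71e-07), and ykgM fell by 6.36 (SE 0.20, adjusted p = 6.91e-08); znuA and znuC had log2 changes of -2.96 and -1.31, while rpmE rose 3.49-fold (log2 change 1.80, and 1.27 and not past the threshold with quantile normalization). Both lists passed camera (adjusted p = 7.7e-16 and 0.00037) and also with an estimated correlation (adjusted p = 0.031 and 0.041).

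Flagellar genes rose at this level. Of 48 members 19 rose and none fell (41 and 0 adjusted over the list alone), with a mean log2 change of 1.06; fliS rose by 2.49, and fliT rose 5.30-fold, flgA 3.42-fold and fliC 3.33-fold. The list passed camera (adjusted p = 6.18e-31, and 0.041 with an estimated correlation). Of 14 acid resistance genes 8 fell and none rose (10 and 0 adjusted over the list alone), with a mean of -1.42: hdeA at -3.36, gadB at -2.91, gadA at -2.43 and gadC at -2.11 (camera adjusted p = 6.99e-12, and 0.041 with an estimated correlation). Of 20 general stress genes 4 fell and none rose (13 and 0 adjusted over the list alone), among them elaB (-1.55); that list passed camera (adjusted p = 1.77e-09), with an adjusted p = 0.11 with an estimated correlation.

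Further lists passed camera with a small positive shift and few or no members past the threshold. Of the branched-chain amino acid genes none passed (2 rose adjusted over the list alone), with ilvN at a log2 change of 1.19 (adjusted p = 0.083); the list had an adjusted p = 0.64 with an estimated correlation. None of the nitrogen limitation or TCA cycle genes passed, over all genes or adjusted over the list alone, with means of 0.28 and 0.37 (adjusted p = 0.28 and 0.73 with an estimated correlation). Of the ribosomal protein genes 1 rose, rpmE (1 adjusted over the list alone), with a mean of 0.23 (adjusted p = 0.80 with an estimated correlation). The glycine list did not pass (adjusted p = 0.45), but 2 of its 14 members rose and none fell (3 and 0 adjusted over the list alone): gcvH 3.88-fold and gcvT by 1.75 on the log2 scale, the latter chosen after its value was seen. The maltoporin gene lamB rose 3.77-fold. In the iron-sulfur assembly, iron uptake, Cpx and respiratory lists no gene passed limma's test at this level; adjusted over the list alone, 1 iron uptake gene fell and 1 Cpx gene rose.

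In all, 85 genes changed at 0.75 mM: 40 rose, 45 fell, and 78 changed at least 2-fold. At an unadjusted p under 0.05 there were 631. For 871 genes (21.1%) the arrays did not overlap, against 10% by chance. The count was 361 with array weights and 72 (64 higher, 8 lower) in the values as deposited, which kept 37 of the 85 and where 9 of the 31 named genes past the threshold lost it (gadC, gadX, yebV, intA, znuC, elaB, yciG, tktB and osmB). So did the branched-chain, nitrogen, TCA and ribosomal lists. All of these lists but nitrogen were also lost with quantile normalization. It was 141 without Cu 0.75 mM replicate 3, the array with high heat shock genes, 45 without Cu 0.75 mM replicate 1, and 54 and 53 without no added Cu replicates 2 and 3. Of the 31 named genes past the threshold 7 lost it in at least one such fit (tktB, osmB, pliG, intA, elaB, yciG and gadX), as did the branched-chain, ribosomal, nitrogen and TCA lists.

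**Figure D2:**
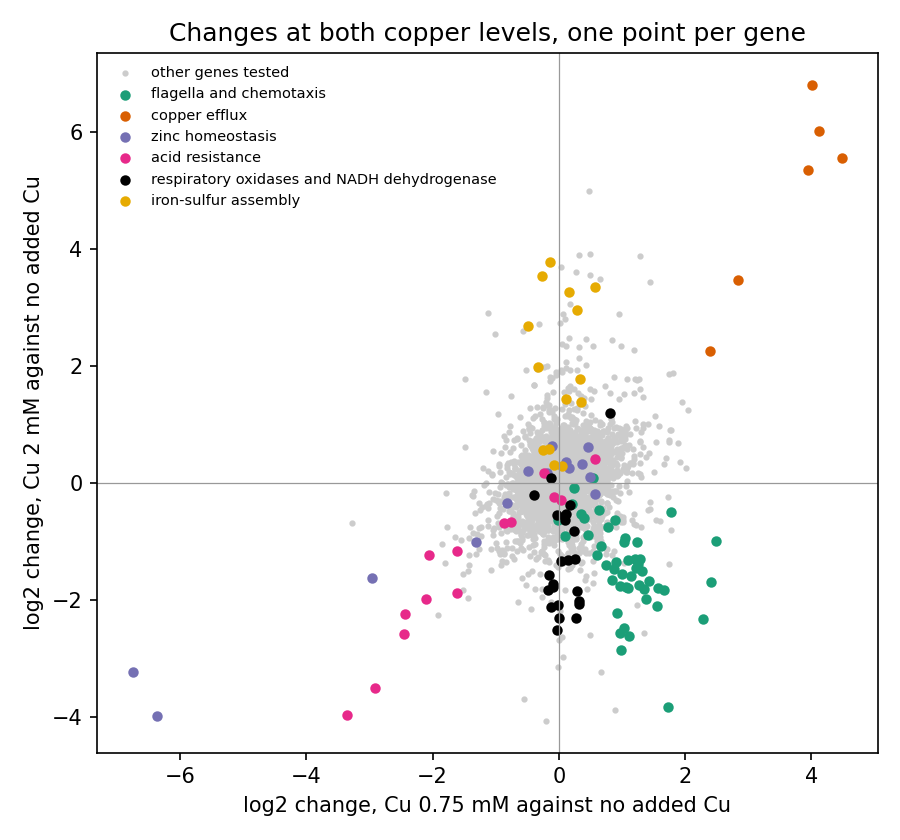
Log2 change of each of the 4128 genes at 0.75 mM copper (x axis) and at 2 mM copper (y axis), each against no added copper, with 6 gene lists coloured. Copper efflux genes lie at the upper right, with means of 3.63 and 4.91, flagellar genes at the lower right, with means of 1.06 and -1.43, and the 4 genes of the zinc list that fell lie at the lower left.

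Between the copper levels, 609 genes differed: 318 were higher and 291 lower at 2 mM than at 0.75 mM. The sharpest list difference was in motility. Of 48 flagellar genes 44 were lower at 2 mM and none higher (46 and 0 adjusted over the list alone), with a mean log2 difference of -2.50; fliC differed by -5.56 ± 0.21 SE (adjusted p = 3.35e-07), fliD by -4.61 and cheW by -3.83. pdeH, a gene of the flagellar regulon that encodes a cyclic-di-GMP phosphodiesterase, differed by -3.91. Of 18 Cpx genes 12 were higher and 1 lower (13 and 1 adjusted over the list alone), spy 22.7-fold and yncJ 16.4-fold higher. These 2 lists also passed with an estimated correlation (adjusted p = 0.028 and 0.021).

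Iron, respiration and ribosome lists that moved at 2 mM also differed between the levels by camera. Of the assembly list 12 were higher and none lower (12 and 0 adjusted over the list alone), sufD 15.1-fold, and of the iron uptake list 23 and 1 (28 and 1 adjusted over the list alone), nrdI 12.6-fold higher; each had an adjusted p = 0.16 with an estimated correlation. sodB was lower by a log2 difference of -4.77. Of the respiratory list 16 were lower and none higher (19 and 0 adjusted over the list alone), nuoG at -2.59, of the anaerobic list 5 and none (7 and 0 adjusted over the list alone), each with an adjusted p = 0.16 with an estimated correlation. Of the TCA list 8 were lower and none higher (10 and 0 adjusted over the list alone), sdhC at -2.08, and of the ribosomal list 32 and none (35 and 0 adjusted over the list alone), rplC at -2.07; both had an adjusted p = 0.20 with an estimated correlation.

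In the zinc list 4 genes were higher and 1 lower at 2 mM than at 0.75 mM (5 and 1 adjusted over the list alone). zinT differed by 3.52 ± 0.27 SE (adjusted p = 2.17e-05), ykgM by 2.37 ± 0.20 (adjusted p = 3.73e-05), znuA by 1.33 ± 0.29 and zupT by 0.75; the call of ykgM was lost with quantile normalization, and the list had an adjusted p = 0.16 with an estimated correlation. The copper efflux list was higher at 2 mM (mean 1.27), with 3 of 6 genes past the threshold and none lower (4 and 0 adjusted over the list alone) and an adjusted p = 0.20 with an estimated correlation. cusF differed by 2.80 and cusC by 1.89, and with quantile normalization by 0.64 and 0.45, not past the threshold. copA differed by 1.06 ± 0.22 SE (adjusted p = 0.0076), which turned to -0.35 with quantile normalization, as the list's mean turned to -0.21. Quantile normalization gives every array the same set of values, so only a gene's rank on its array remains. That setting therefore cannot compare sizes among the highest genes. cueO differed by -0.13 (95% interval -0.58 to 0.31, adjusted p = 0.71).

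Other lists that passed were lost with an estimated correlation. Higher at 2 mM were the other copper-linked genes (7 of 17, 8 adjusted over the list alone, hprR 4.08-fold; adjusted p = 0.19 with an estimated correlation), superoxide (6 of 17, 6 adjusted over the list alone, soxS 7.14-fold; adjusted p = 0.29 with an estimated correlation), general stress (3 of 20, 3 adjusted over the list alone, osmB 2.97-fold; adjusted p = 0.48 with an estimated correlation) and phage shock (2 of 7, 3 higher and 1 lower adjusted over the list alone, pspA 2.57-fold; adjusted p = 0.20 with an estimated correlation). Lower were purine (4 of 14, 10 adjusted over the list alone, guaB at -1.12; adjusted p = 0.19 with an estimated correlation), histidine (3 of 8, 3 adjusted over the list alone, hisC at -1.20; adjusted p = 0.29 with an estimated correlation) and aromatic amino acid genes (4 lower and 1 higher of 18, 5 and 1 adjusted over the list alone, trpE at -1.13; adjusted p = 0.37 with an estimated correlation). In the acid resistance list no gene differed between the levels (mean 0.0036, camera adjusted p = 0.98).

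The count between the levels was 386 at a 2-fold minimum, 401 with quantile normalization, 196 (61 higher, 135 lower) in the values as deposited, 545 (226 higher, 319 lower) with centring on all spots and 1000 with array weights. Of the 68 named genes past the threshold 27 lost it in the values as deposited (copA, msrP, fepA, znuA, zupT, fldA, inaA, nfo, trpC, trpE, aroD, trpD, hisC, hisH, hisA, guaB, purT, cvpA, purL, dmsB, rpsS, rplO, osmB, osmC, bolA, pspA and pspE) and 15 with quantile normalization (copA, cusC, cusF, hprR, cusR, ykgM, zupT, yccA, fldA, inaA, nfo, aroD, hisA, purL and pspE). The copper efflux, superoxide and phage shock lists were lost with quantile normalization, and the aromatic, histidine, general stress and phage shock lists as deposited. Without Cu 0.75 mM replicate 1 it was 374, and 12 of the 68 named genes past the threshold lost it in at least one fit without an array (cusC, zupT, trpD, hisA, purT, cvpA, purL, pspE, aroD, inaA, nfo and ansB), as did the histidine, general stress, aromatic and phage shock lists.

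**Figure D3:**
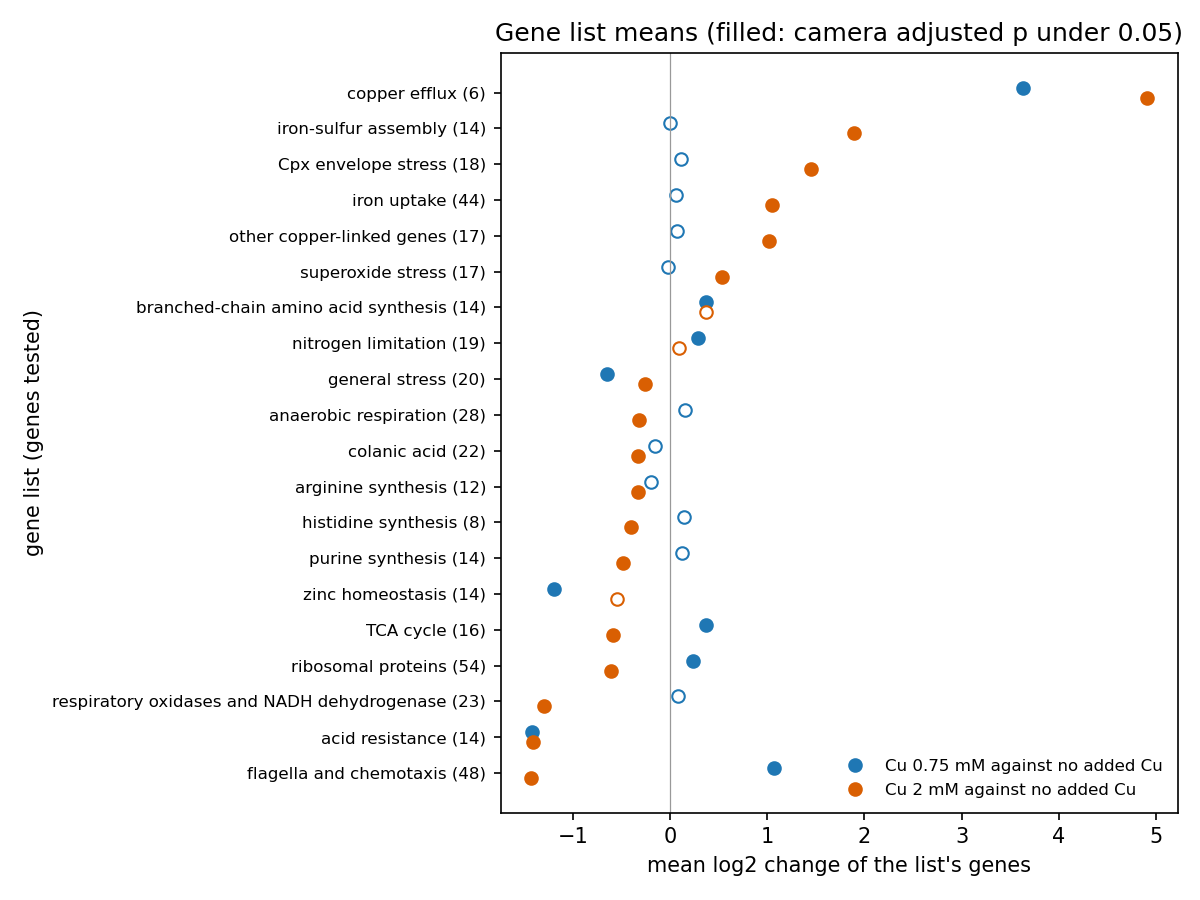
Mean log2 change (x axis) of the gene lists (y axis, with the number of genes tested) that passed camera in at least one comparison with no added copper; blue points are 0.75 mM, orange points 2 mM, and filled points passed at an adjusted p of 0.05 with the preset correlation. The flagella list lies on opposite sides of 0 (1.06 and -1.43), and the acid resistance list at -1.42 for both levels.

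The calls at both levels against no added copper overlapped in both directions. In the same direction 34 genes were called, 12 higher and 22 lower, where independent lists would share 2.01 and 2.25. In 100 simulations of random noise, unchanged groups with shared simulated controls had 0.03 in common on average. Unchanged groups give almost no calls at an adjusted p of 0.05, so that value is near 0 by design. At an unadjusted limma p under 0.01, 67 genes were shared in the same direction, against 6.79 in the simulations. In opposite directions 21 genes were called, 20 of them lower at 2 mM and higher at 0.75 mM, where independent lists would share 2.00; 17 of the 21 are flagellar genes. The log2 changes correlated across genes at 0.26, below the simulated 0.50 for unchanged groups with shared controls, with a covariance of 0.089 against 0.041, a difference of 0.049. Because 3 control arrays cannot be split, part of the excess of shared calls over independent lists may come from the shared controls. The simulated values include shared controls, but for unchanged groups only.

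The cultures without added copper were compared with the pool, which came from other cultures without added copper. The pool was a single RNA preparation whose own error is not in the test, and with one channel order a dye effect on a gene cannot be separated from a difference. By limma the mean ratio of 372 genes differed from 0, 130 higher and 242 lower, of which 49 differed at least 2-fold. Without no added Cu replicate 3 there were none and without replicate 1 there was 1, against 67 without replicate 2; at an unadjusted p under 0.05 the 3 arrays together gave 1212. The count was 892 with quantile normalization, 833 with equal spread per array and 53 (2 higher, 51 lower) in the values as deposited.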

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

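The single-array test of the flagellar genes, the test of compressed ratios in the form given here, the tests of spot and array noise and both tests of the heat shock genes were chosen after the result was seen; the others were written before.

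Between the copper levels, 21 genes were called in opposite directions against no added copper, and this difference between groups drew attention to them; that all 21 were also called between the levels follows from that choice and adds nothing to it. Besides 17 flagellar genes they were osmB, pdeH, ykfB and ymdA, chosen after their values were seen. The flagella and chemotaxis list differed between 2 mM and 0.75 mM by a mean log2 change of -2.50. Its genes have 96 spots in 25 of the 48 blocks, and with each block centred on its own median the difference was -2.43 (SE 0.13), which argues against the position of the spots as the whole cause. Leaving out each of the 9 arrays in turn, the smallest difference was -2.43 (SE 0.13), which argues against one aberrant array. Arrays without added copper do not enter this difference, so only the fits without a copper array bear on it. The copper level itself and growth rate, oxygen or other differences between the cultures at harvest stay open and were not tested.

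The zinc-responsive genes zinT, ykgM and znuA fell less at 2 mM than at 0.75 mM, at 0.48, 0.63 and 0.55 of the log2 change. If ratios on the 2 mM arrays were compressed, other genes would be too. Over 41 genes outside the zinc list called lower at 0.75 mM, the median ratio of the changes was 0.57 (95% bootstrap interval 0.37 to 0.72). Over 81 called there in either direction it was 0.31 (interval 0.10 to 0.60), with genes of opposite sign at the 2 levels among them. Choosing genes by their 0.75 mM change lowers this ratio by itself. A first form, written before, took the 30 genes called alike at both levels (0.999, interval 0.90 to 1.06) and leaves out small changes at 2 mM. The means of the 3 preset lists that passed at both levels in the same direction had ratios of 1.35 (copper efflux), 0.997 (acid resistance) and 0.41 (general stress, whose 2 mM mean of -0.26 turned to 0.070 as deposited and lost its call with one array left out), so compressed ratios and a difference by copper level cannot be told apart here, because each choice of genes leans one way and the lists are few. For zinT and ykgM the largest difference between the spots of a gene or the arrays of a copper group was 33.5% of the difference between the levels. This argues against random noise of dim spots, but an error shared by spots and arrays would not show here. For znuA the largest such difference was 99.4%, from the arrays at 0.75 mM, which does not decide. The znuA difference between the levels of 1.33 (SE 0.29) passed limma's test, a call lost in the values as deposited. This noise test was first run on spots alone and was split by gene after that result was seen.

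Heat shock genes were high on Cu 0.75 mM replicate 3 alone: log2 ratios of 1.88 for dnaK, 2.03 for dnaJ and 1.81 for groL, where no other array exceeded 0.50, 0.48 and 0.46. The dnaK control spots of this array were raised by over 1 (log2), against the other 0.75 mM arrays, in 48 of the 48 blocks, which argues against a flaw on part of the array. Of the 15 other list members 9 were highest on this array, which argues against a fault of the dnaK probe. This array shares its group and conditions with the other arrays at 0.75 mM, and the labels name nothing that sets it apart, so no biological explanation was tested; handling of this culture stays open.

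Spots without a gene name in the table used here were tested apart from the genes. Of 5312 such spots 7 changed at 2 mM against no added copper, 6 higher and 1 lower; they stand out as a signal in data outside the gene comparisons. Among them 3 pairs of adjacent spots changed alike, and the pair with the largest change, at spot 8611, reached a log2 change of 4.65 ± 0.46 SE (adjusted p = 0.0052).

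Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. The real split was 1 of the 10 with as many genes at 2 mM (413, highest other 0), at 0.75 mM (85, highest other 0) and between the levels (609, highest other 0). For gene lists by camera, 1 split gave as many at 2 mM (17, highest other 14) and 1 between the levels (17, highest other 14), whereas 4 gave at least the 9 lists of the 0.75 mM comparison (highest other 12). The other splits mix arrays of both real groups. They keep part of any true shift and add the rest to the spread, so they do not stand for unchanged groups.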

How the results depend on the processing

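Block-wise centring, centring on all spots, keeping control spots and leaving out discordant spots were chosen after seeing the data. Genes changed at 2 mM against no added copper numbered 413, and 143 as deposited, 265 with quantile normalization, 1321 against the pool and 258 to 479 with one array left out; 250 of the 413 remained with quantile normalization and 132 as deposited. At 0.75 mM the count was 85, of which 37 remained as deposited, and 361 with array weights, 862 against the pool and 45 to 141 with one array left out. Between the levels it was 609, and 386 at a 2-fold minimum, 196 as deposited, 401 with quantile normalization, 1000 with array weights and 374 to 711 with one array left out. Cultures without added copper differed from the pool in 372 genes, and in 49 at a 2-fold minimum, 53 as deposited, 892 with quantile normalization, 833 with equal spread and 0 to 470 with one array left out. A stricter size, fewer arrays or no control spread account for part of this by construction. As deposited, arrays of a group differed in level (gene medians -0.67, 0.36 and 0.66 at 2 mM), which adds to the spread of genes. Quantile normalization and equal spread widen the arrays without added copper (SD over genes 0.46 to 0.53, against 0.73 to 0.84 at 2 mM). This moves their ratios to the pool away from 0. How far each accounts for the counts, and other causes, were not tested.

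Lists past camera's threshold numbered 17, 9 and 17 at 2 mM, at 0.75 mM and between the levels, and 3, 4 and 2 with an estimated correlation; as deposited the 0.75 mM count was 5. With one array left out the counts were 14 to 18, 5 to 11 and 15 to 18. The overlap of calls in the same direction was 34, and 67 at an unadjusted p of 0.01, where simulated unchanged groups with shared controls gave 6.79. Directions turned between the levels with quantile normalization for copA (-0.35), cusB (-0.41), cusA (-0.76) and the copper efflux list (-0.21). That method gives every array the same set of values, so a gene's value depends only on its rank on the array. Why these directions turned was not tested. hisG at 2 mM, not past the threshold, turned to 0.030 as deposited, where leaving out centring moves all genes alike, and to 0.16 against the pool. cueO between the levels ranged from -0.26 to 0.0076 with one array left out, turning without Cu 0.75 mM replicate 1. For hisG against the pool and for cueO the cause was not tested.

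Samples shared only a number: same-numbered arrays of different groups correlated at -0.02 to 0.24 in their deviations, 5 of 9 pairs over 0.1, and 7 of 9 arrays correlated best with their own number, a hint from the data and not from the design. With the replicate block the counts were 407, 96 and 611 genes and 17, 9 and 17 lists; 369 of 413, 78 of 85 and 553 of 609 genes were called in both fits, and wcaC, ugd, argE and dmsB at 2 mM and yciG and osmB at 0.75 mM were not past the threshold with the block. Of 201 gene results, leaving out one array gave 1663 values with the same direction and side of the threshold, 131 no longer past it, 8 newly past it and 1 turned. Signal over background was not used here, so what it limits is unknown.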

Other observations

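Neighbouring genes outside the lists changed together at 2 mM copper. The biotin synthesis genes bioB, bioF, bioC and bioD rose against no added copper by a mean of 1.41 on the log2 scale (0.93 to 1.74), and thiH, thiG, thiF, thiE and thiC of thiamine synthesis rose together with the neighbouring gene rsd by a mean of 0.99 (0.65 to 1.24). All 5 genes of the oligopeptide importer, oppA, oppB, oppC, oppD and oppF, fell, with a mean of -2.22 (-2.68 to -1.74). Between the copper levels, the multidrug efflux genes mdtA, mdtB, mdtC and mdtD, the adjoining sensor-regulator genes baeS and baeR and yegP were higher at 2 mM by a mean of 1.24 (0.71 to 1.91), and ygbN, rpoS, nlpD and pcm by a mean of 0.97. These genes were chosen after their values were seen, as members of runs of at least 4 neighbours called alike.

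There were 17 such runs at 2 mM, 3 at 0.75 mM and 21 between the levels, most of them runs of listed genes. In 10000 permutations of the calls over the genes the highest numbers were 2, 1 and 3 (permutation p = 1e-04 in each, the smallest they can give). Permuting treats the calls of neighbours as independent, which they are not where neighbours are transcribed together. The small p therefore says only that calls cluster along the genome, whatever their cause. None of the 4127 pairs of neighbouring genes had spots in a shared block, and with each block centred on its own median the numbers were 17, 3 and 23. The glycine cleavage genes gcvP, gcvH and gcvT formed a run with ygfF at 2 mM, at a mean of 1.29; glycine was added with the copper, so the effect of either cannot be separated by this design.

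On Cu 0.75 mM replicate 2, the 3 dnaK control spots at the start of the first block had a median log2 ratio of 1.70, where the median over all 312 dnaK control spots of that array was -0.47. Block medians spanned 0.40 to 1.37 on the log2 scale within an array.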
